A study of Anopheles gambiae and Anopheles coluzzii with 6 samples.

How the data were processed

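The series holds 6 Agilent 2-colour expression arrays. Each array was hybridised with RNA from the heads of field-caught Anopheles coluzzii, labelled with Cy3, and with RNA from the heads of laboratory mosquitoes, labelled with Cy5. Anopheles coluzzii is an African malaria mosquito whose males gather in swarms at dusk, where mating takes place. Per the labels' protocols, the swarming mosquitoes were netted in swarms at dusk and were mostly males, and the non-swarming ones were males resting in houses, aspirated shortly before swarming time while the hairs of their antennae were becoming erect. Total RNA was extracted with Trizol followed by a CTAB step that removes melanin, and 200 ng were labelled with the Low Input Quick Amp kit, per the labels' protocols. The labels describe 3 biological replicates in each group. How many heads went into a replicate is not given in the sources used here. The dyes were not swapped, so any dye or strain effect common to the 6 arrays stays in a log ratio and drops out of the comparison of the groups only as far as it is the same on every array.

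The deposited scanner files give spot brightness as intensity on a linear scale, made by Agilent Feature Extraction 10.5.1.1 per the file headers. The files also hold processed intensity values, background-subtracted, detrended and dye-normalised by that software per the file headers, and a log10 ratio of Cy5 over Cy3, also per the file headers. The authors further deposited a value table of 16378 of the 43603 probes on a log2 scale. Its processing is not described in the sources used here, apart from Partek, which the submitters' processing notes name without a version or a step. Set against the scanner files of the same array, each column of that table correlated across probes with the log10 ratio of Cy5 over Cy3 at between −0.98 and −0.99, with slopes between −3.18 and −3.22, so its scale is log2 and its direction Cy3 over Cy5. Its columns are not centred on 0: the medians were 0.47, 0.29 and 0.22 for swarming 1 to 3 and 0.30, 0.27 and 0.21 for non-swarming 1 to 3. How its probes were filtered stays unknown. It served as an alternative only.

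The log2 ratio of Cy3 over Cy5 was computed from mean spot signals and median local backgrounds with limma 3.58.1 in R 4.3.3. Background was corrected with normexp (offset 50) and each array was normalised with loess, control spots at weight 0. Spots that the scanner software had marked as outliers in either channel were left out. For spots with an uneven local background this was done before normexp, a change of order made after a first fit had been seen. There were 164 such spots, most of them on the swarming 1 array. With them in, the log ratios of swarming 1 correlated across genes with those of the other arrays at 0.63 at most, and no gene passed the threshold, and the order was changed with that count known. With those spots out, its highest correlation was 0.98. The fit with the spots kept is reported among the alternatives. No spot was saturated in either channel.

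Spots of a probe were averaged. Probes entered if Cy3 was well above background on all 3 arrays of at least 1 group, which left 33058 probes. Gene identifiers came from the annotation columns of the scanner files, which are as old as the array design. Of all probes, 28318 carried a single gene identifier of the form AGAP and a number, 529 carried several and 14756 none. Probes of an identifier were averaged, and probes without one were grouped by the transcript or probe name in the files, giving 14907 gene units. Of these, 383 had a product name in the files. For a few genes the identifier had been paired with a name (timeless, period, Clock, cycle, Pdp1, the desaturase, CYP4G16, saglin and vitellogenin among those named in the text) before the data were examined, from general knowledge of the published annotation. The files themselves pair no name with these identifiers, and no table was at hand to check them. Probe positions are those of the array annotation, whose header gives the genome build as anoGam1 (MOZ2). Whether every position follows that build was not tested. No genome or gene models were used here, so exon, intron and UTR positions are not given.

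Groups were compared by limma's moderated test (lmFit and eBayes, group as the only term) with Benjamini-Hochberg adjustment over the 14907 units and a threshold of 0.05. Gene lists were fixed before the data were examined: core clock, cuticular hydrocarbon and fatty acid synthesis, odorant-binding and chemosensory proteins, chemoreceptors, vision, takeout and juvenile hormone, neuropeptides, transmitter signalling, cytochrome P450s, glutathione transferases with esterases and UGTs, cuticular proteins, innate immunity, heat shock, glycolysis with trehalose and glycogen, ribosomal proteins, salivary gland, gut enzymes, and female fat body and ovary. Lists for muscle, oxidative phosphorylation and axonemal genes found no member in the annotation, and the list for testis and male accessory gland had no member above background. The salivary text pattern for D7 proteins also matched glutathione S-transferase D7, which was taken out of that list after the match was seen. A list was tested with camera (preset correlation 0.01) if at least 5 of its genes were measured, which 9 lists met, with an estimated correlation and fry beside it, and the group term was the one tested in every fit with a block. Members were matched by product name or pre-set identifier, so genes without a name in the files are missing from the lists.

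The genes named were set by a rule fixed before the data were examined. It takes every measured clock gene and up to 12 of the cuticular hydrocarbon genes. It takes the 12 largest rises and falls past the threshold that have a product name and groups that do not overlap, and where fewer pass, genes of smallest unadjusted p up to 6 in a direction. It adds the 3 genes of smallest p in each other list, and the largest rise and fall whatever their annotation. A gene that the rule takes is not reported here, and no other took its place. No gene past the threshold had a product name in the files, so the product-named genes were all taken by unadjusted p. AGAP006009 and the units discussed by position were chosen after their values were seen.

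The slide and scan of each array were read from the file headers. Swarming 1 and 2 were on slide 1 and swarming 3 shared slide 2 with the 3 non-swarming arrays, and the scans split in the same way. The slide was tried as a fixed block, as a random block, and by using slide 2 alone. Other alternatives were no background subtraction, Agilent's processed signals, median centring, Aquantile, Cy3 alone after quantile normalisation, no filter on dim probes, a filter on both channels, probes as units, medians of probes, replicate number as a block, array weights, a trended robust variance, the deposited table, and each array left out in turn. Leaving out swarming 1 and non-swarming 3 together was added after the data were seen. Every gene named was measured on arrays of both groups, so no fold is given as a bound. AGAP006009 and AGAP002588 were dim in non-swarming heads, though above background on all 3 arrays. Their normalised log2 Cy3 levels there were 6.07 and 6.23, near the 5.95 of period, which passed on 1 of those arrays. The size of their folds is therefore uncertain.

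The fit was tested on simulated log ratios of 14875 units for swarming versus non-swarming, with 200 changed. It called 80 of 100 units changed by 1 on the log2 scale and 97 of 100 changed by 2, with 8 false calls and no call in the wrong direction. The changes were added to ratios as they stand after loess, with independent noise and no slide or array effect. With 200 units changed, the adjusted threshold is also easier to pass than where fewer change. So these shares are not the chance of calling such a change in RNA. Precision is limited by the number of arrays, 3 in a group.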

Results

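Gene expression in the heads of swarming and non-swarming mosquitoes was measured on 6 arrays, 3 in each group, as the log2 ratio of the field sample (Cy3) to a laboratory reference (Cy5). The field channel was the brighter. Between 32593 and 35039 of the 43603 probes were well above background in Cy3 and between 18329 and 22980 in Cy5. Log ratios of arrays of the same group correlated across genes at 0.97 to 0.99, and those of arrays of different groups at 0.96 to 0.98 (genes are not independent replicates). The first principal component held 43.8% of the variance and ran from swarming 1 at −31.0 to non-swarming 3 at 28.6. The second held 24.2% and separated the groups, with swarming arrays at 5.49, 17.2 and 13.8 and non-swarming arrays at −17.5, −16.3 and −2.63. Swarming 1 also had 57 gene spots with an uneven local background, against 4 to 22 on the other arrays.

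The design sets swarming against non-swarming mosquitoes, which asks which head transcripts differ between mosquitoes, mostly males, flying in a swarm and males at rest shortly before it. In swarming heads the clock gene timeless, which encodes the light-sensitive partner of PERIOD in the circadian feedback loop of flies, was 2.74-fold higher, and the units AGAP002588 and AGAP006009, which have no name in the files, were 11.4-fold and 11.3-fold higher. In all, 17 of 14907 gene units changed, 16 higher and 1 lower, with limma's moderated test at an adjusted p below 0.05. With slide as a fixed block, or within slide 2, the count was 0. None of the 17 had a product name in the files, and timeless was named through an identifier set beforehand. In all 17 the swarming arrays did not overlap the non-swarming arrays, which held for 12.3% of all units, against 10% by chance for 3 against 3.

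Among the 6 measured clock genes, 1 rose and none fell over all genes tested, and 3 passed when adjusted over the list alone. This list was one that the study followed up, so the second count is not independent evidence. The timeless log ratio (AGAP008288, probes at 3R from 8595831 to 8600927) was −0.69 ± 0.13 in swarming and −2.15 ± 0.09 in non-swarming heads (SD, n = 3 each). Its change was 1.45 with an SE of 0.10 and an adjusted p of 0.0086, and its 6 probes gave changes from 1.05 to 2.19. Under 7 of 24 alternatives, slide as a fixed block among them (1.30, adjusted p 0.27), the call was lost with the direction kept, with adjusted p over the alternatives from 0.0022 to 0.80. Pdp1, which encodes a PAR-domain activator of the Clock gene in flies (AGAP006376, 2L from 30208910 to 30257423), had a change of 1.20 with an SE of 0.16, past the threshold over the list alone but not over all genes, where its adjusted p was 0.078. Under 8 of 24 alternatives it passed over all genes, as with Cy3 alone (1.46, adjusted p 0.0042). The third to pass over the list alone was cycle, which encodes the partner of CLOCK in activating transcription (AGAP005655, 2L from 17768940 to 17769003). Its change was −1.55 with an SE of 0.38 and an adjusted p of 0.34 over all genes, and the 3 swarming values lay below the 3 non-swarming ones. It was −0.97 with slide as a block, −0.91 with median centring and −3.02 with Cy3 alone, where its adjusted p was 0.021. Cryptochrome 2 at 0.47 ± 0.23 (SE), period at −0.23 ± 0.09 and Clock at 0.02 ± 0.10 did not pass in the ratio. The probes averaged for a clock gene did not always agree. The 2 of cryptochrome 2 were at −0.21 and 1.14, and the 8 of Clock ran from −0.27 to 0.76. The 4 of Pdp1 ran from 0.168 to 1.599, while the 3 of cycle lay between −1.71 and −1.40. The sign for period turned with median centring (0.014) and with Cy3 alone (0.26). That for Clock turned with both (−0.52 and −0.75) and with Agilent's processed signals (−0.46). With Cy3 alone Clock passed over all genes as lower, with an adjusted p of 0.048 by limma. Cryptochrome 2 turned when slide entered as a block (−0.024). The single period probe was well above background on 1 of the 3 non-swarming arrays.

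**Figure D1:**
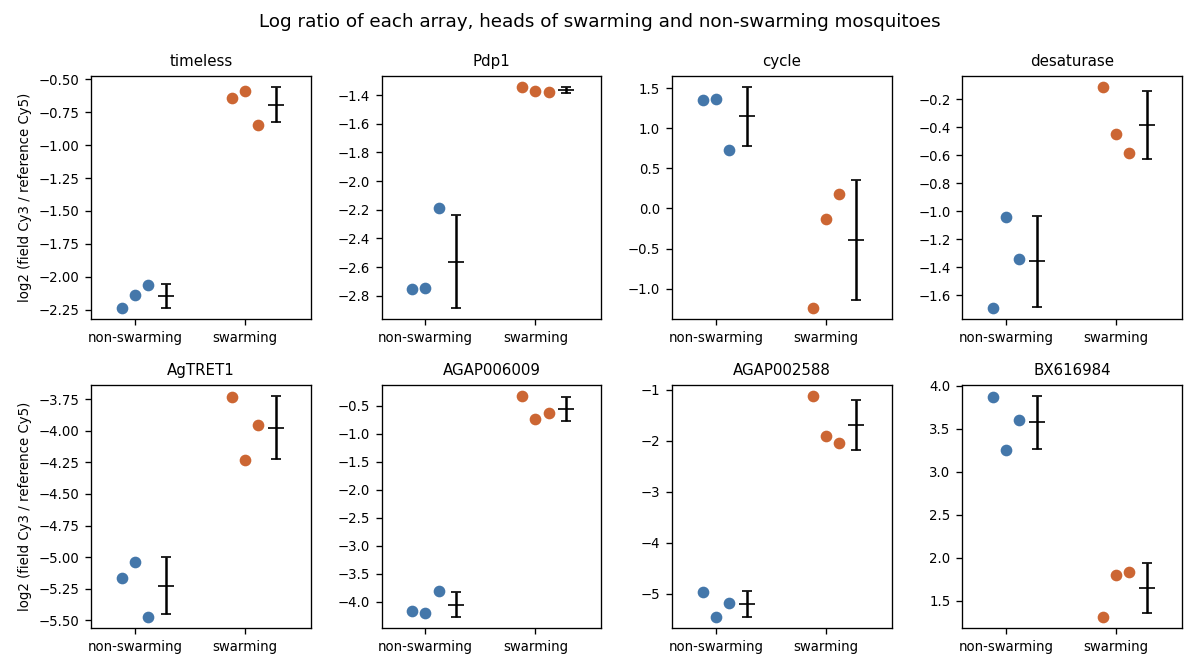
Log2 ratio of field Cy3 to reference Cy5 for 8 gene units, 1 panel each with its own vertical scale (horizontal axis, group). Points are the 3 arrays of a group, the bar beside them is the mean with its SD, and the groups do not overlap in any panel, as for timeless with means of −0.69 in swarming and −2.15 in non-swarming heads.

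The largest rise was that of AGAP002588 (2R from 23314048 to 23314857), with a log ratio of −1.69 ± 0.49 in swarming and −5.20 ± 0.25 in non-swarming heads (SD, n = 3 each), a change of 3.51 and an adjusted p of 0.0086. Its 11 probes disagreed in size, from 0.12 to 4.52. AGAP006009 (2L from 24070875 to 24071053), the unit of smallest p, named after its values were seen, changed by 3.49 with an SE of 0.16 and an adjusted p of 0.0017. The only fall, that of BX616984 (3R from 52011783 to 52011842), was by 1.93 with an SE of 0.20 and an adjusted p of 0.033. It reached 0.40 in the other direction with Agilent's processed signals. The files pair none of these 3 units with a name. Over the alternatives the call was lost under 7 of 24 for AGAP002588, 3 of 24 for AGAP006009 and 15 of 22 for BX616984, the setting that turned its sign included.

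Genes of cuticular hydrocarbon synthesis, which make the waxes of the body surface that also serve as contact signals in insects, were covered by only 2 measured members, both past the threshold when adjusted over the list alone and neither over all genes. The study followed up a desaturase too, so that count is not independent evidence either. The desaturase AGAP001713 (2R from 8874940 to 8875781) was at −0.38 ± 0.24 in swarming and −1.36 ± 0.33 in non-swarming heads (SD, n = 3 each), a change of 0.98 with an SE of 0.20 and an adjusted p of 0.22. Its 3 probes ranged from 0.17 to 2.26. With Cy3 alone its change was 1.78 and its adjusted p 0.0022, in a range from 0.0022 to 0.997 over the alternatives. CYP4G16, an oxidative decarbonylase of the last step of that pathway (AGAP001076), had a change of −0.42 with an SE of 0.15, of −0.26 with slide as a block and of −0.78 with Cy3 alone (adjusted p 0.034).

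Of the list of glycolysis, trehalose and glycogen, 3 genes were measured and none passed over all genes, while 2 passed when adjusted over the list alone. The trehalose transporter AgTRET1, which carries the blood sugar of insects across membranes (2L from 16510919 to 16510978), had a change of 1.25 with an SE of 0.17 and an adjusted p of 0.078. Trehalose-6-phosphate phosphatase, the last enzyme of trehalose synthesis, had a change of 0.67 ± 0.12 (SE) and glycogen phosphorylase, which releases glucose from glycogen, one of 0.43 ± 0.21. Adipokinetic hormone I, which mobilises stored fuel in insects, was at 0.71 with an SE of 0.16 and an adjusted p of 0.30, and it was the 1 neuropeptide gene of 7 to pass when adjusted over the list alone. It was at 0.34 with slide as a block or within slide 2, at 0.36 with Cy3 alone and at 1.36 in the deposited table. The other product-named genes of smallest p on the higher side were serpin 5, a serine protease inhibitor, at 0.95 (adjusted p 0.078), the cytochrome P450 CYP325G1 at 0.60 (0.099), and a cytoplasmic carbonic anhydrase at 0.69 (0.17). On the lower side the antigen 5-related 2 protein was at 0.41 in swarming and 1.41 in non-swarming heads. The CLIP-domain protease ser6 had a change of −0.94, CYP6M1 one of −0.98, bacteria responsive protein 2 one of −0.78 and the antimicrobial peptide cecropin one of −0.73, with adjusted p from 0.29 to 0.40 over these 5. The chaperone gene HSP83, the only measured member of the heat shock list, was at −1.21 with an adjusted p of 0.48, and passed over its list alone, a single test. Swarming 1 was the lowest array (0.55, against 1.70 and 1.94), and the change was −0.79 without it, −0.67 with slide as a block and −0.44 with Agilent's processed signals.

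**Figure D2:**
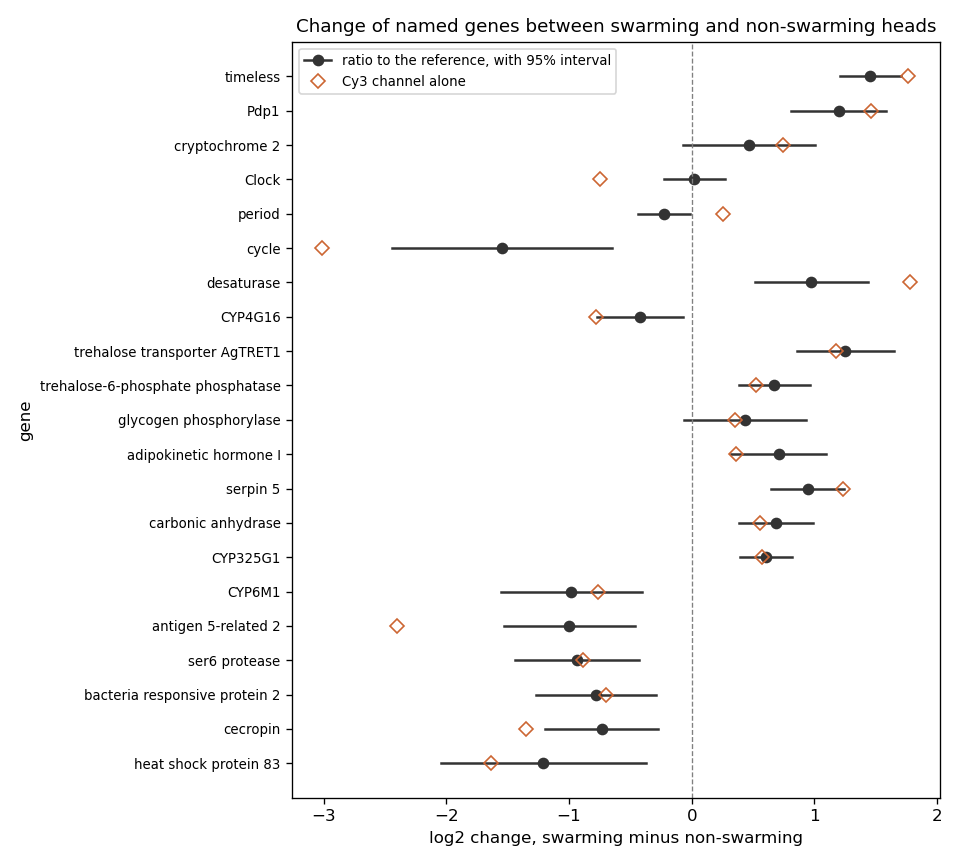
Log2 change between swarming and non-swarming heads of 21 named genes (horizontal axis, positive values are higher in swarming). Filled points with bars are the ratio to the reference with its 95% interval and open diamonds the Cy3 channel alone, with timeless at 1.45 and 1.76, cycle at −1.55 and −3.02, and Clock and period on opposite sides of 0 by the ratio and by Cy3.

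None of the 9 lists tested shifted by camera with an adjusted p under 0.05. At an unadjusted p under 0.05 there was 1, and fry called 1. The 31 odorant-binding and chemosensory proteins, which carry odorants in the sensillum lymph, had the smallest camera p, 0.0094 (adjusted p 0.084, and 0.37 with an estimated correlation), with 20 members above and 11 below 0 and a median change of 0.15. With slide as a block its unadjusted camera p was 0.013, and within slide 2 it was 0.012. Its 3 members of smallest p were OBP5470 at 0.59, OBPjj17 at 0.37 and OBP5479 at 0.39. Of these, OBPjj17 was at −0.27 with Agilent's processed signals, −0.98 with median centring and −1.33 with Cy3 alone. The falls with median centring and with Cy3 alone passed over all genes (limma's adjusted p 0.042 and 0.028). The clock list had an adjusted camera p of 0.29 in the upward direction (0.69 with an estimated correlation), and with slide as a block an unadjusted one of 0.50 in the same direction and within slide 2 one of 0.81. Fry gave it an adjusted p of 0.025. That test asks whether the members move in the same direction on balance, without setting them against other genes. The 6 members include timeless, itself called, and 4 were above and 2 below 0. With slide as a block the fry p of the clock list was 0.0087, unadjusted.

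Of 49 cytochrome P450s none passed over all genes in the ratio and CYP325G1 passed over the list alone. With Cy3 alone, P450s that the naming rule did not take were called too. Among them were changes of 2.34, 2.24 and −0.92 (limma's adjusted p 0.0022, 0.0027 and 0.018). In the ratio these genes were at −0.11, −0.23 and −0.0034. The list's adjusted camera p was 0.53. CYP9K1 had a change of 1.56 with an SE of 0.47, with an SD of 1.02 among the swarming arrays, and it was at 0.60 with slide as a block or within slide 2 and at 1.02 without swarming 1. The 22 innate immunity genes, with 8 above and 14 below 0, had an adjusted camera p of 0.29 in the downward direction, and with slide as a block an unadjusted one of 0.95 in the upward direction. Lysozyme i-2 was at 0.36. Adjusted camera p was 0.31 for the 12 transmitter genes, led by acetylcholine receptor subunits alpha 9 at 0.29 and alpha 3 at 0.39 and the GABA-gated chloride channel at −0.19. It was 0.70 for neuropeptides, with the short neuropeptide F receptor at −0.20 and the myosuppressin receptor at 0.25. It was 0.70 for the 13 glutathione transferases and related enzymes, whose median of −0.028 and mean of 0.044 differed in sign, with glutathione S-transferase D7 listed as separate units at 0.42 and 0.57 and gst3-8 at 0.25. Of these signs, those of acetylcholine receptor alpha 3, the chloride channel, both receptors and gst3-8 turned with Cy3 alone, that of the chloride channel also with median centring and that of the myosuppressin receptor also with Agilent's processed signals. With slide as a block the changes of acetylcholine receptors alpha 9 and alpha 3 and of the myosuppressin receptor were 0.12, 0.065 and 0.030. With slide as a block the unadjusted camera p of the 6 lists other than the odorant-binding, clock and immunity ones lay between 0.27 and 0.94, and within slide 2 that of the 8 lists other than the odorant-binding one lay between 0.14 and 0.94.

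Markers of other tissues and of females did not pass. The 8 salivary genes had an adjusted camera p of 0.51 in the downward direction, with a median of −0.047 and a mean of 2.7e-04, and they held gSG2-like protein at −0.22, F1 protein at −0.23 and saglin at −0.13. F1 protein turned sign with median centring and Cy3 alone, and saglin with Cy3 alone. The 8 gut enzymes had an adjusted camera p of 0.77, with ISPR10 at −0.18 and the maltases Agm2 at 0.15 and Agm1 at 0.13, the last at −0.21 with Agilent's processed signals. The yolk protein gene vitellogenin was at 0.13 ± 0.13 (SE). Lists with too few members to test held arrestin Arr1 at 0.44 ± 0.56 (SE), methoprene-tolerant at −0.22, ribosomal proteins S6 at 0.42 and S26 at −0.13, the cuticular proteins CP2b at −1.01 ± 0.96 and CPR147 at −0.03, and odorant receptor 2 with gustatory receptors 24 and 22 at 0.07, 0.06 and −0.02. Of these, S26, CPR147 and the 3 receptors changed sign under at least 1 other scaling, and Arr1 and S6 with slide as a block (−0.31 and −0.26).

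Slide and group were partly confounded, since only swarming 3 shared slide 2 with the non-swarming arrays and sets the contrast once slide is a fixed block. The count was then 0 with limma. The 633 units at an unadjusted p under 0.05 were fewer than the 0.05 share of 14907 units that would pass with no change. With the block the changes were 1.30 ± 0.13 (SE) for timeless, 1.18 ± 0.25 for Pdp1, −0.97 ± 0.47 for cycle, 0.77 ± 0.27 for the desaturase, 3.16 ± 0.33 for AGAP002588, 3.43 ± 0.23 for AGAP006009 and −1.74 ± 0.29 for BX616984. The count was 1 without swarming 2, 1 without non-swarming 2, 4 without swarming 3 and 11 without swarming 1. It was 0 with the uneven spots kept, the order of steps used first and given up after that count was seen. There 382 units had an unadjusted p under 0.05 by limma, also below the share of 0.05. Median centring called 179 units, 70.9% of them higher, and Cy3 alone called 544, 57.5% of them higher, against 94.1% of the 17. Among the named genes that the ratio did not call, Cy3 alone called 13 in the direction of the ratio. Besides Pdp1, cycle, the desaturase and CYP4G16, these were serpin 5, CYP325G1, the antigen 5-related 2 protein and ser6. They also held lysozyme i-2, both units of glutathione S-transferase D7, OBP5479 and Agm2. Cy3 alone further called Clock at −0.75 and OBPjj17 at −1.33 (limma's adjusted p 0.048 and 0.028), both against the direction of the ratio.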

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

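All tests in this part, the count over other splits included, were chosen after the results they bear on had been seen. The Cy5 channel carried laboratory mosquitoes on every array, and no comparison of the report uses it alone. Taken alone, it differed between swarming and non-swarming arrays in 15 genes at limma's adjusted p under 0.05. That is a signal in a channel that should be alike on every array, and 14 of the 15 were also called in Cy3 alone. At an unadjusted p under 0.05 there were 871, little above the 0.05 share of units that would pass with no change. Cycle had a change of −2.08 in Cy5 and −3.02 in Cy3, and 3 of the 15 were among the report's 17 called units, with changes of 1.16 to 1.87 in Cy5, at 1.36 the fragment on 3R that lies beside timeless. The 10 splits of the 6 arrays are too few for a share under 0.05: 1 split, the real one, gave as many as 15, and the highest of the others gave 1.

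Among the 253 genes called in Cy3 that were at least 4 times brighter in Cy3, the Cy5 change followed the Cy3 change with a slope of 0.53 ± 0.02 (SE), against 0.038 ± 0.011 among the 70 that were at least as bright in Cy5. A candidate explanation is that part of the Cy3 signal, or of the field RNA, was read in Cy5, and these 2 routes are not separated by the values at hand. Laboratory reference RNA that itself differed between the groups' arrays stays open, since its changes need not follow Cy3, and 4 of the 15 genes changed more in Cy5 than in Cy3 or in the other direction, which carry-over alone would give only through noise. No biological explanation was tested, as the reference is no group of the study.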

How the results depend on the processing

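Dim Cy5 signal and 3 arrays in a group limit the comparison. The count of 17 changed units (16 higher, 1 lower) stayed within 1.5 times without background subtraction, with Aquantile, without the dim filter, with both channels above background, with medians of probes and with slide as a random block. Aquantile leaves the log ratios as they are, so its fit is the same by construction. The random block had an estimated correlation of −0.019, so its fit is close to that without a block. Neither is a check on the count. Otherwise it was 1 (1 and 0) with Agilent's processed signals, 179 (127 and 52) with median centring, 544 (313 and 231) with Cy3 alone, 72 (65 and 7) per probe, 0 (0 and 0) with slide as a fixed block or within slide 2, 73 (51 and 22) with array weights, 9 (9 and 0) with a trended robust variance and 2 (2 and 0) in the deposited table. Keeping the uneven spots, as in the first fit, whose count was seen before they were left out, gave 0 (0 and 0). Chosen after seeing the data, leaving out swarming 1 and non-swarming 3 together gave 52 (44 and 8). The count of lower genes was 0 without background subtraction and without the dim filter. Leaving out 1 array gave 1 to 16 changed, 1 to 15 higher and 0 to 4 lower units, and 0 to 1 shifted lists. Lists shifted were 1 with Agilent's processed signals, 4 per probe, where 13 lists could be tested, 1 with fry, and 0 in the other settings apart from the arrays left out. The cause was not tested, apart from the fewer arrays in slide 2 and in the fits that leave arrays out.

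With the replicate number as a block (replicate block), 31 units changed, 23 higher and 8 lower, and 15 of them were among the 17. The deviations of same-numbered arrays correlated at 0.34, −0.07 and 0.39, and those of differently numbered arrays at −0.44 to 0.22. Not every array correlated best with its own number. Whether the numbers pair the arrays stays undecided.

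Of 1232 values of the 53 named genes under the alternatives, 1099 kept direction and side of the threshold and 68 changed sign. With the direction kept, 31 lost the call and 34 gained one. The values with Aquantile, which leaves the log ratios as they are, keep both by construction. The sign changes were of genes not called in the report, except BX616984, and the cause was not tested. Those of Clock with Cy3 alone and of OBPjj17 with median centring and Cy3 alone also passed the threshold, in the turned direction. Genes left out by a setting have no value there. The changed signs were as follows. Without background subtraction 0.012 for gustatory receptor 22, 0.025 for CPR147. With Agilent's processed signals −0.17 for gustatory receptor 24, −0.10 for the myosuppressin receptor, −0.46 for Clock, −0.27 for OBPjj17, 0.0074 for gustatory receptor 22, −0.21 for Agm1, 0.40 for BX616984. With median centring 0.12 for the GABA-gated chloride channel, 0.014 for period, −0.011 for gustatory receptor 24, −0.52 for Clock, −0.98 for OBPjj17, 0.12 for F1 protein, −0.0074 for odorant receptor 2, 0.018 for gustatory receptor 22. With Cy3 alone 0.22 for the GABA-gated chloride channel, −0.21 for acetylcholine receptor alpha 3, 0.052 for saglin, 0.26 for period, −0.032 for gustatory receptor 24, −0.12 for the myosuppressin receptor, −0.75 for Clock, −1.33 for OBPjj17, 0.63 for F1 protein, −0.064 for gst3-8, −0.054 for odorant receptor 2, 0.033 for gustatory receptor 22, 0.12 for rpS26, 0.12 for the short neuropeptide F receptor. With both channels above background −0.065 for Clock. Per probe 0.11 for cecropin, −0.013 for Agm1. With the median of probes −0.089 for Clock. With slide as a block or within slide 2 −0.040 for gustatory receptor 24, −0.024 for cryptochrome 2, −0.11 for Clock, 0.0073 for gustatory receptor 22, −0.31 for Arr1, −0.26 for ribosomal protein S6. With array weights 0.10 for CPR147. In the deposited table −0.44 for Clock, −0.70 for OBPjj17, 0.17 for gustatory receptor 22, −0.47 for Agm1. With the uneven spots kept 0.41 for ser6, 0.39 for CP2b. Without both swarming 1 and non-swarming 3 0.082 for CPR147, −0.53 for Arr1, −0.33 for ribosomal protein S6. Leaving out 1 array gave ranges of −0.028 to 0.087 for Clock, −0.032 to 0.010 for gustatory receptor 22, −1.60 to 0.16 for CP2b, −0.13 to 0.065 for CPR147, −0.051 to 0.83 for Arr1, −0.11 to 0.76 for ribosomal protein S6.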

Other observations

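Across the 6 arrays, the field heads also differed from the laboratory reference, a contrast with no dye swap and no test, in which strain, rearing and dye stand together. Of 230 product-named units above background in Cy5 on every array, the photoreceptor protein arrestin Arr1 had the highest mean log ratio, 5.09 ± 0.83 (SD, n = 6). Calmodulin followed at 4.13 ± 0.33 and an inhibitor of phenoloxidase, the enzyme of melanin formation, at 3.71 ± 0.26. The odorant-binding proteins OBP-8 and OBP-4 were at 2.72 ± 0.30 and 2.07 ± 0.18, and OBPjj11 at −5.46 ± 0.41. At the low end stood trehalose-6-phosphate phosphatase at −7.76 ± 0.39 and acetylcholine receptor subunit alpha 2 at −7.12 ± 0.37.

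Some of the 17 called units lay side by side, as seen after the calls were made. A called transcript fragment on 3R (8601701 to 8601760), at 0.88 with an adjusted p of 0.028, starts 774 bases beyond the last timeless probe. A pair of other called units, at 1.29 and 1.65, overlap on 3L from 24081184 to 24081421. So the 17 units stand for fewer than 17 separate positions. Not every unit nearby was called. BX021648, BX021649 and TC125477, which overlap the span of the timeless probes, were at 0.050, 0.026 and 0.26. Beside the pair on 3L, AGAP011460 was at 0.016, AGAP011459 at 0.59 and CR535893, which overlaps the pair, at 0.71. None of these passed the threshold.

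The tests in the rest of this part were chosen after the results had been seen, except the test on the held-out array and the count of gene lists over splits. Cy3 alone called 544 genes, all 17 of the reported ones among them. If the slide set those calls, swarming 3 would lie with the non-swarming arrays of its slide. In the 128 genes called in Cy3 without swarming 3, the held-out array showed a median of 0.93 of the change (quartiles 0.82 and 1.01), which argues against slide as the whole cause, although slide as a block left 13 calls and slide 2 alone 1. The loess curve is a candidate explanation for the gap, since over the 544 genes the loess-corrected change was a median of 0.46 of the median-centred one. The median-centred change was a median of 0.81 of the Cy3 change, between the bounds set for and against a part of the reference channel, so that part stays open.

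The last pair of tests replaced earlier forms after their values were known. The first form compared the loess-corrected ratio with Cy3 directly, a median of 0.29, which holds the loess curve and the reference channel together. A larger spread between replicates was also looked at, and the median residual SD was 0.15 for the ratio and 0.13 for Cy3 alone.

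Timeless and Pdp1 stood higher and cycle lower in swarming heads, though in the ratio only timeless passed the threshold over all genes, while with Cy3 alone all 3 did. Within slide 2 the lowest share of the change that any of these 3 genes kept was 0.63, that of cycle, whose change with slide as a block was −0.97 ± 0.47 (SE), against 1.30 ± 0.13 for timeless and 1.18 ± 0.25 for Pdp1. Slide and group cannot be told apart for these genes, because only swarming 3 shares the slide and, unlike in the test above, the genes were chosen with the values of that array. A later hour of catching may give such a pattern whatever the mosquitoes did. Transcripts of timeless and of Clock, the partner of cycle, peak at opposite times of day in flies. The change of cycle, −1.55, has the opposite sign to that of timeless, but the phase of cycle itself is not given here. Clock was at 0.02 in the ratio and −0.75 with Cy3 alone, where its adjusted p by limma was 0.048. Period, which peaks with timeless in flies, was at −0.23 in the ratio and 0.26 with Cy3 alone. Catching hour and swarming cannot be told apart, because the swarming group was netted at dusk and the other group was taken before it.

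The splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 17 changed genes (16 higher, 1 lower) and the highest of the other splits 0, so 1 split gave as many. With Cy3 alone these were 544 and 0. By the count at limma's unadjusted p under 0.05, the real split did not stand out. It gave 1116 units, against 2533 for swarming 1 with non-swarming 1 and 2. Swarming 1 and 2 with non-swarming 1 gave 1145, and the rest gave between 194 and 847. For gene lists the real split gave 0 and the highest other 2, so all 10 splits gave as many.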
